A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

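RNA was measured in 6 samples of budding yeast, 3 of a strain that carries the artificial data-carrying chromosome (dChr) and 3 of a control strain with an empty plasmid. Per the labels' protocols, both strains were grown at 30 °C in synthetic medium lacking uracil, diluted from a 4 ml overnight culture into 50 ml at an optical density of 0.2, and harvested between 1.0 and 1.2. Total RNA was column-purified and sequenced on Illumina instruments. The labels do not say whether the 3 samples of a strain came from separate cultures, so the p-values measure the spread between these samples.

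The deposited values are TPM (a length-normalized abundance scaled to the same total in each library) in a single table of 7554 transcripts and 6 libraries. Per the submitters' processing notes, cutadapt 2.6, HISAT2 2.0.5, StringTie 2.0, DESeq2 (no version given) and R 3.6.0 were used with the sacCer3 build; the role of each tool, the strand setting and any filter are not given in the sources used here. TPM keeps no sequencing depth, so the depth of each library is unknown, and no counting interval or detection floor is given. The TPM of a library sum to between 970077 and 992087, 0.791% to 2.99% below the full TPM scale, so some transcripts are not analysed here. Of the 7554 transcripts, 643 are assembled transcripts with names of the MSTRG form and no coordinates. Gene names and positions of 6011 transcripts came from a RefSeq annotation of the yeast reference assembly, matched by locus tag or name.

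Values were analysed as log2(TPM + 1). Transcripts with a mean of at least 1 TPM over the 6 libraries were tested (5938 transcripts), with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend), dChr against control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on the log2(TPM + 1) scale and understates the change of transcripts with low values. The model had no term for the replicate number, because the labels do not say that a number marks a shared day. TPM are not counts, so no count model was used.

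Gene lists (33, of which 32 had at least 3 tested members) were written down before the data were examined, and tested with camera (inter-gene correlation preset at 0.01), with camera at an estimated correlation, and with fry. Camera sets the members of a list against all other tested transcripts. Fry asks only whether the members changed, so its p-value does not answer the question that camera asks. Beside each list stand the members that passed over all transcripts and those that passed when p-values were adjusted over the list alone. The 16 nuclear chromosomes were tested as sets in the same way, with an exact permutation of the labels, whose smallest p is 0.1 for 3 against 3. A transcript was counted as detected in a single strain at 1 TPM or more in the 3 libraries of that strain and exactly 0 in the other 3.

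The rule for the genes named in the text was also fixed before the data were examined. It took the 12 transcripts with the largest positive and the 12 with the largest negative change among those past the threshold whose libraries did not overlap between strains. It added, per list, the 2 called members with the smallest p in each direction, or else the 2 with the highest mean TPM. The auxotrophic markers URA3, HIS3, LEU2, LYS2, MET17, TRP1 and ADE2, the mating-type-specific genes, the 8 core histone genes and transcripts detected in a single strain were taken whatever their values. HIS3 is not analysed here. Genes outside this rule are marked where they are named as chosen after their values were seen, apart from RPP1, which a list pattern took in by name.

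The fit was tested on simulated data in which 200 of 5938 transcripts were changed. The simulated noise was normal and independent between transcripts, with the residual SD of each. The real data also hold correlated genes and single libraries far from their strain, so recovery and false calls may differ there. The fit recovered 31.3% of the transcripts changed 1.5-fold, 70.1% of those changed 2-fold and 86.4% of those changed 4-fold, and 6 of its 131 calls were false (4.58%). The alternatives tried were other pseudocounts (0.1 and 5), other filters, median-ratio scaling, quantile normalization, removal of mitochondrial and non-coding transcripts, other variance models, array weights, a replicate block and leaving out each library. Removal of the assembled transcripts was added after seeing the data. Scripts used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Near-identical gene copies and overlapping genes share reads, and without a stated strand setting a gene and its antisense partner cannot be separated, so values of such genes are uncertain.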

Results

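Transcript levels were compared between 2 yeast strains with 3 libraries each. yMH007 carries dChr, an artificial chromosome built to store data, and yMH104, the control, carries an empty plasmid; both grew in medium lacking uracil. The study asked whether such foreign DNA is transcribed and, with it, how the host transcriptome compares. Protein-coding transcripts took 41.2% to 48.8% of the TPM of a library, non-coding transcripts 18.2% to 34.7% and assembled transcripts 20.3% to 34.9%. Pearson correlations of log2 values over transcripts were 0.904 to 0.940 within a strain and 0.897 to 0.928 between strains. The first principal component held 30.2% of the variance and placed the dChr libraries between -28.9 and -20.9 and the control libraries between 16.9 and 31.8. The second held 22.6% and set the control libraries far apart, at -32.7, 43.0 and -9.99 for control libraries 1, 2 and 3. The dChr libraries lay between -3.42 and 5.64 on it.

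The first comparison was of every transcript between the strains. Chaperone genes were among the largest rises in the dChr strain: BTN2, a factor that gathers misfolded proteins, stood at 639 ± 63.1 TPM against 49.3 ± 25.6 in the control (SD, n = 3), and HSP42, a small heat shock protein, at 46.4 ± 22.3 against 3.80 ± 1.06. The largest fall was in PHO84, the high-affinity phosphate transporter, at 3.97 ± 0.475 TPM against 159.5 ± 12.2 (log2 fold change -5.01 ± 0.11 SE, limma adjusted p = 3.45e-06). SNO1 and SNZ1, a divergent gene pair of vitamin B6 synthesis, fell by 4.63 and 3.97 on the log2 scale. The arginine genes ARG1 and ARG3 fell by 4.27 and 4.28, ARG1 from 684 ± 114 TPM in the control to 35.5 ± 11.7.

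In all, 249 transcripts rose and 544 fell of 5938 tested (13.4%), 73 and 195 of them at least 2-fold. Among protein-coding genes 217 rose and 489 fell of 5082. The libraries of the strains did not overlap for 34.1% of transcripts, where chance gives 10%. The split between directions depended on the scaling: 507 rose and 638 fell with median-ratio scaling, 555 and 561 with quantile normalization, and 192 and 711 without mitochondrial and non-coding transcripts. Without the assembled transcripts, an alternative added after seeing the data, 150 rose and 364 fell. Without dChr library 1 the counts were 113 and 282, without dChr library 2 124 and 397, without dChr library 3 158 and 307, and without control library 3 147 and 417.

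**Figure D1:**
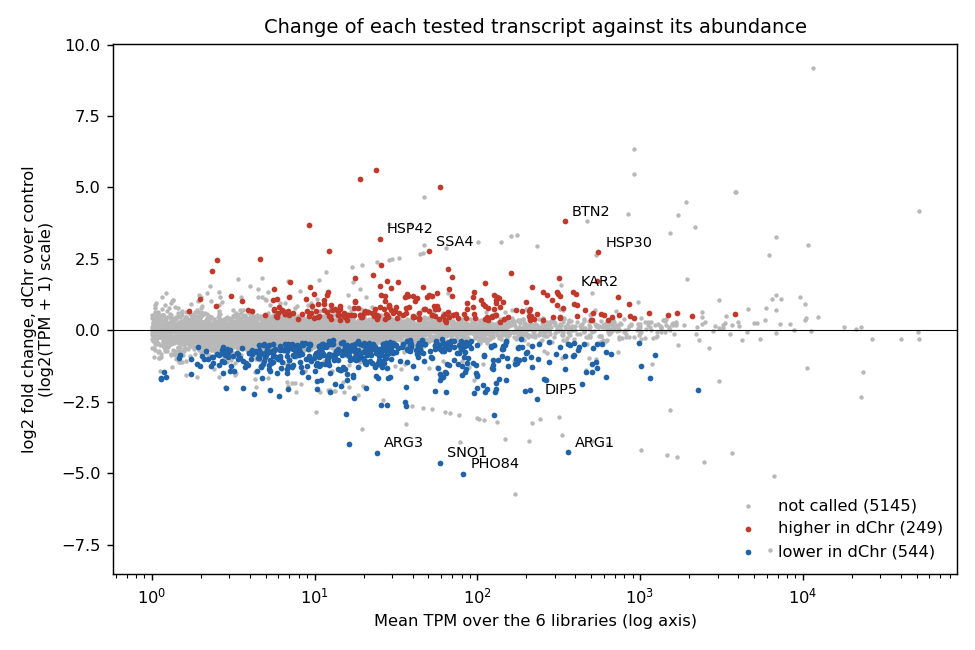
Log2 fold change of each of 5938 tested transcripts (dChr over control, log2(TPM + 1) scale) against its mean TPM over the 6 libraries on a log axis, with 249 higher transcripts in red, 544 lower ones in blue and the rest in grey. Some abundant transcripts with large fold changes are grey, which means that they were not called.

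Chaperone and stress genes rose together. Of 25 tested heat shock factor targets and chaperones, 19 rose and 0 fell (23 and 0 when adjusted over the list alone), with a median log2 fold change of 0.92. SSA4, a stress-induced Hsp70, rose from 12.1 ± 0.946 to 88.7 ± 12.2 TPM (limma adjusted p = 0.000167), and HSP78, a mitochondrial disaggregase, from 63.5 ± 3.97 to 260.5 ± 32.3. Of 53 genes of the induced environmental stress response, 32 rose and 0 fell (36 and 1 adjusted over the list alone), with a median of 0.76. ALD3, a stress-induced aldehyde dehydrogenase of this list, rose by 2.76. HSP30, a plasma membrane stress protein that is in neither list, rose by 2.74, from 144 ± 22.1 to 960.1 ± 72.7 TPM. The lists share 5 members. Camera called both higher (adjusted p = 5.11e-19 for chaperones and 5.05e-21 for the stress response), and neither call held with an estimated correlation (adjusted p = 0.532 and 0.542). Fry, which does not compare the members with other transcripts, gave adjusted p = 0.00408 and 0.0122. Of all 32 lists camera called 8 higher and 7 lower at the preset correlation and 0 with an estimated correlation (1 at an unadjusted p under 0.05). Fry called 8, of which 2 were higher and 6 lower.

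Genes for making amino acids fell in the dChr strain. Of 54 tested amino acid biosynthesis genes, 47 fell and 0 rose (48 and 0 adjusted over the list alone), with a median log2 fold change of -1.04. ASN1, an asparagine synthetase, fell from 320.4 ± 28.3 to 72.1 ± 6.62 TPM, and BAT2, a branched-chain aminotransferase, from 149.6 ± 8.91 to 50.5 ± 1.51. ARG5,6 (listed as ARG56) fell by 2.62 and LYS2 by 1.22 on the log2 scale. ARG7 stood at 34.6 ± 27.7 TPM against 217 ± 28.7 (limma adjusted p = 0.0232), a call lost without dChr library 3 or any single control library (adjusted p from 0.0622 to 0.0727). Camera called the list lower (adjusted p = 4.67e-26), and with an estimated correlation adjusted p = 0.532.

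Sulfur and nitrogen genes shared this direction. Of 26 sulfur amino acid genes 13 fell and 1 rose (16 and 1 adjusted over the list alone): STR3, which acts between cystathionine and homocysteine, fell by 2.92, and SUL2, a sulfate permease, fell by 1.77, while SAM2, an S-adenosylmethionine synthetase, rose by 0.52. SAM2 lost its call without any single library except control library 3. Of 25 genes under nitrogen catabolite repression 12 fell and 0 rose (14 and 0 adjusted over the list alone). GAP1, the general amino acid permease, fell from 89.6 ± 6.15 to 19.9 ± 1.49 TPM, and AGP1 from 204.2 ± 13.6 to 56.5 ± 3.68. The permease gene DIP5, which is in neither list, fell by 2.42. Camera called both lists lower (adjusted p = 6.87e-06 and 6.43e-06), and with an estimated correlation adjusted p = 0.575 for each.

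Ribosome biogenesis genes fell, while few ribosomal protein genes were called. Of 105 ribosome biogenesis genes 40 fell and 0 rose (58 and 2 adjusted over the list alone), with a median of -0.57. NSR1, a nucleolar protein, fell from 120.3 ± 7.30 to 40.5 ± 9.99 TPM. Of 133 genes of the cytosolic ribosomal protein list 3 rose and 2 fell (0 and 2 adjusted over the list alone), with a median of 0.13. RPS28B fell by 1.04 and RPL22B fell by 0.86. Each has a second gene copy, and reads can be shared where the copies match. The name pattern of this list also took in RPP1, a subunit of RNase P and not a ribosomal protein, which was not called. Camera called biogenesis lower and ribosomal proteins higher (adjusted p = 7.72e-14 and 2.54e-05), and with an estimated correlation adjusted p = 0.620 and 0.766. Fry called neither (adjusted p = 0.0504 and 0.320).

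The phosphate regulon and mating genes also fell. Of 13 phosphate regulon genes 6 fell and 0 rose (8 and 0 adjusted over the list alone), with PHO84 first and SPL2, a regulator of phosphate transport, at 0.867 ± 0.356 TPM against 7.64 ± 0.953. PHO84 overlaps a non-coding gene, and the strand setting is not given. Of 7 genes specific to a cells 6 fell (6 adjusted over the list alone): STE2, the alpha-factor receptor, went from 375.6 ± 29.3 to 174.3 ± 9.61 TPM, BAR1, the protease that cuts alpha-factor, from 129.7 ± 3.85 to 57.7 ± 2.71, and MFA1, an a-factor gene, from 64.1 ± 7.57 to 30.0 ± 3.29. The call of STE6 was lost without dChr library 1 or 3 (adjusted p = 0.0564 and 0.0582), and that of ASG7 without any single library except control library 2. Of 12 haploid and pheromone response genes 5 fell and 0 rose (10 and 0 adjusted over the list alone), among them AGA1, which fell by 1.36. Camera called the 3 lists lower (adjusted p = 1.09e-05, 5.95e-05 and 7.32e-05), and with an estimated correlation adjusted p = 0.532, 0.532 and 0.542.

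Camera at the preset correlation called 5 further lists higher, none of them called by fry. Of all tested protein-coding genes 217 of 5082 rose. In the iron regulon 5 genes rose and 1 fell of 23 (7 and 2 adjusted over the list alone), with FET3, the iron oxidase, at 452.9 ± 29.6 TPM against 195 ± 27.8. In the unfolded protein response 2 of 14 rose (2 adjusted over the list alone), KAR2, the Hsp70 of the endoplasmic reticulum, by 1.36 and ERO1 by 1.22, while the list median was 0.05 and turned to -0.03 without mitochondrial and non-coding transcripts and also without control library 1. In the proteasome list 2 of 32 rose (1 adjusted over the list alone), RPN4, its transcription factor, by 1.23. In the cell wall integrity list 3 of 17 rose (3 adjusted over the list alone), CWP2 by 0.95. Of 18 glycolysis and fermentation genes 2 rose (1 adjusted over the list alone), ENO1 by 0.59, a call lost without dChr library 1 or 2. The other, GLK1, is also in the stress response list. It rose by 0.49 (limma adjusted p = 0.0483), a call lost when any single library was left out. Under the glycolysis list lie TDH3, TDH2, ENO2, PGK1 and PGI1, chosen after their values were seen. Each had at least 1 library 4-fold or more from the others of its strain. TDH3 was at 6.43 TPM in control library 2 against 15466 in the other controls. Camera gave adjusted p = 0.0089, 0.0347, 0.00175, 0.00263 and 0.0155 in this order, and with an estimated correlation adjusted p = 0.645, 0.739, 0.620, 0.645 and 0.575. Fry gave adjusted p = 0.116, 0.0980, 0.116, 0.101 and 0.0507. The iron call was lost without control library 3 (adjusted p = 0.0511), that of the unfolded protein response without dChr library 3 or control library 1 (0.0524 and 0.148), and that of glycolysis without control library 2 or with quantile normalization (0.0829 and 0.876).

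**Figure D2:**
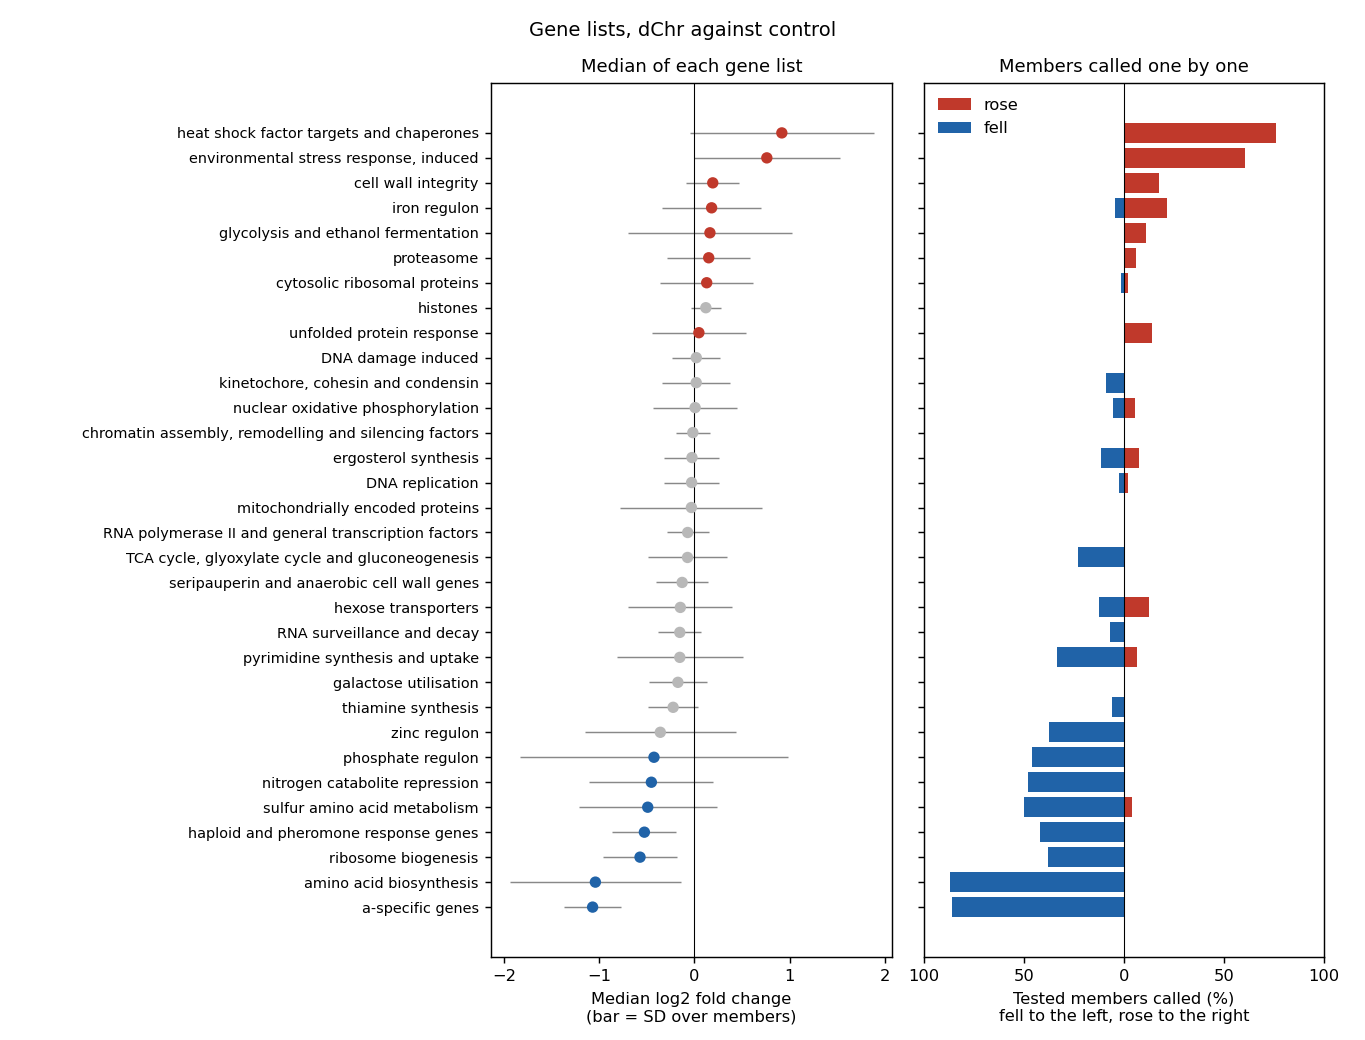
Median log2 fold change of the tested members of each of 32 gene lists with the SD over members (left; red and blue, lists called higher and lower by camera at the preset correlation), and the percentage of members that rose or fell (right). Chaperones have the highest median, 0.92, and a-specific genes the lowest, -1.07.

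The next comparison was of the selection marker and of genes for chromatin and transcription, since the strains differ in added DNA. URA3, which the medium without uracil selects for, stood at 43.4 ± 3.53 TPM in the dChr strain and 42.4 ± 6.56 in the control (limma adjusted p = 0.881). ADE2 was at 79.2 ± 9.79 against 78.8 ± 6.93, and TRP1 at 18.3 ± 1.37 against 19.6 ± 3.41. MET17 was listed at 0 in the 6 libraries, and LEU2 was at 0 or under 1 TPM in each. Of 10 tested histone genes 0 were called by limma, 0 at an unadjusted p under 0.05: HHT2 was at 640.4 ± 37.8 against 617.9 ± 47.6 TPM and HTB2 at 571.2 ± 47.9 against 530.2 ± 75.7. HHT1, which shares its protein sequence with HHT2, was at 416.4 ± 297 against 433.5 ± 296 TPM, with libraries of either strain far apart. Limma called 0 of 44 chromatin assembly, remodelling and silencing factors (2 at an unadjusted p under 0.05) and 0 of 29 genes of RNA polymerase II and general factors (3 at an unadjusted p under 0.05). RPO21, its largest subunit, was at 131.4 ± 11.99 against 109.8 ± 8.23 TPM. It also called 0 of 17 genes induced by DNA damage (1 at an unadjusted p under 0.05), where RNR2 was at 496 ± 8.92 against 476 ± 24.0 TPM. Camera called none of these 4 lists (adjusted p = 0.172, 0.543, 0.930 and 0.455), and in the simulated data 31.3% of 1.5-fold changes were recovered. With median-ratio scaling and with quantile normalization RPO21 (adjusted p = 0.0146 and 0.0267) and SPT16, a histone chaperone subunit of the chromatin list (0.0363 and 0.0374), were called higher.

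**Figure D3:**
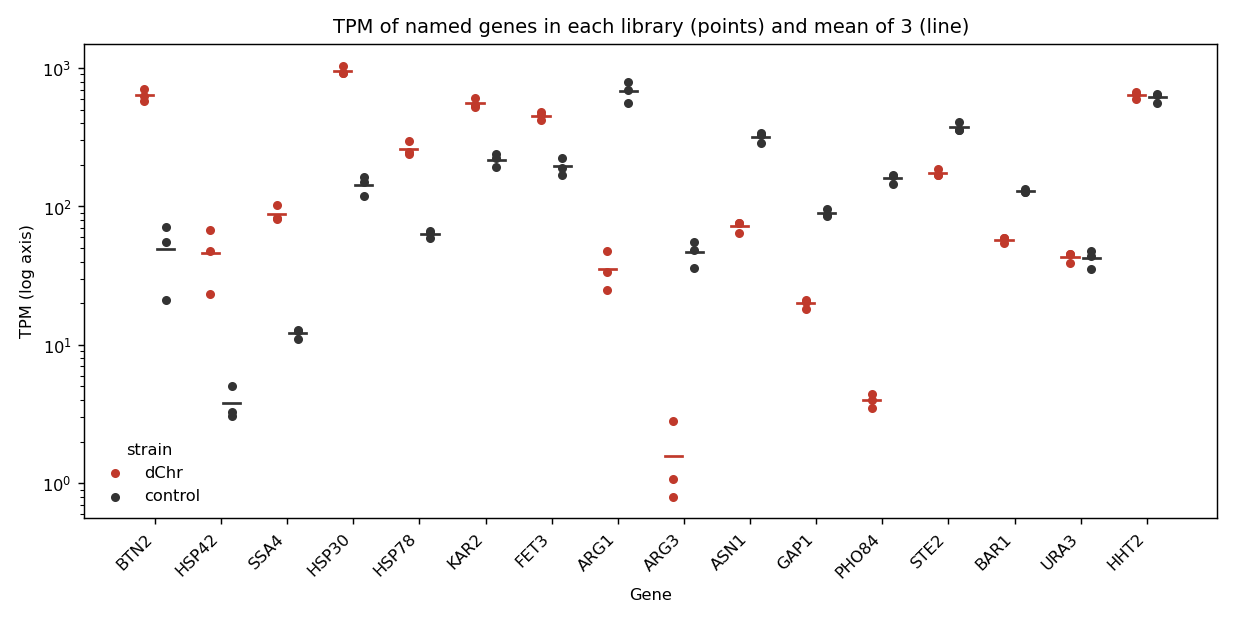
TPM on a log axis of 16 named genes in each of the 3 dChr libraries (red points) and 3 control libraries (black points), with a line at each mean. The strains do not overlap for BTN2 to BAR1, while URA3 and HHT2 overlap.

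The table held transcripts that are not annotated yeast genes, and these were compared as possible features of the artificial chromosome. Assembled transcripts MSTRG.2154.1 and MSTRG.2798.1 stood at 47.5 ± 3.12 and 38.3 ± 3.33 TPM in the dChr strain and were listed at 0 in the 3 control libraries (limma adjusted p = 3.45e-06 for each). Control values that are all 0 add no spread, so p-values of such transcripts do not measure any spread in the control. MSTRG.6671.2 was at 5.05 ± 2.78 TPM and at 0 in the control, but MSTRG.6671.1, by its name another transcript of the same assembled locus, was at 113.3 ± 6.61 TPM in the dChr strain and at 10.1, 1.08 and 0.956 TPM in the control libraries. MSTRG.5899.1 was at 43.4 TPM in dChr library 2, at 6.24 and 5.51 TPM in the other dChr libraries and at 0 in the control, and its call was lost without any single control library (adjusted p from 0.0570 to 0.0630). In the other direction MSTRG.3305.1 and the open reading frame YJL064W were at 2.28 ± 1.15 and 2.27 ± 0.424 TPM in the control and at 0 in the dChr strain. Of 571 tested assembled transcripts 22 rose and 41 fell. The table gives them no coordinates, so whether any lies on the artificial chromosome or in the yeast genome is not known here. The processing notes name sacCer3 as the only genome build, and whether reads were also aligned to the dChr sequence is not known here. If they were not, these transcripts would lie in the yeast genome. Values of 0 can be failed estimates: 69 of 643 assembled transcripts were at 0 in a library and at 100 TPM or more in another, against 1 of 6911 annotated ones.

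The last comparison asked whether any yeast chromosome differed as a whole. The median log2 fold change of the genes on a chromosome differed from that of all transcripts by between -0.04 (chromosome XV) and 0.08 (chromosome III). Camera called 0 of 16 chromosomes, 0 at an unadjusted p under 0.05 (smallest adjusted p = 0.993). In an exact permutation test, two-sided, no chromosome can go below p = 0.1, and 6 of the 16 (II, III, IV, XII, XIV and XV) were at this value.

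The following genes each have a single coding exon on the R64 reference. BTN2 is at chromosome VII 772454 to 773686, HSP42 at chromosome IV 806621 to 807748, SSA4 at chromosome V 364589 to 366517 and HSP30 at chromosome III 156109 to 157107. PHO84 is at chromosome XIII 24037 to 25800, ARG1 at chromosome XV 219211 to 220473, ARG3 at chromosome X 268799 to 269815 and GAP1 at chromosome XI 515063 to 516871. SNO1 at chromosome XIII 457285 to 457959 and SNZ1 at 458408 to 459301 are neighbours on opposite strands.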

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

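Without the assembled transcripts, an alternative chosen after seeing the data, 150 transcripts rose and 364 fell. With median-ratio scaling 507 rose and with quantile normalization 555, of which 248 and 242 were among the 249 of the reported fit; the cause was not tested. Leaving out a library gave 113 to 262 rises and 282 to 417 falls, with fewer samples in each fit. The lowest counts of rises came without dChr library 1 (113), dChr library 2 (124), control library 3 (147) and dChr library 3 (158), and those of falls without dChr library 1 (282) and dChr library 3 (307). With a pseudocount of 5, which shrinks low values by construction, 162 transcripts changed at least 2-fold (55 higher and 107 lower). Of gene lists, 15 were called by camera, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 8 by fry. Requiring 5 TPM left 3 transcripts detected in a single strain, each in dChr. No chromosome was called under any alternative run. Among named genes 159 results lost their call and 8 gained it, and none that was called changed direction. Among lists, beyond the estimated correlation, the haploid list lost its call with a mean of at least 10 TPM (adjusted p = 0.0612), and the pyrimidine and zinc lists gained theirs with quantile normalization (adjusted p = 0.0391 for both), the pyrimidine list also without dChr library 3 (0.0352).

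With a replicate block in the model, 268 transcripts rose, 566 fell, 259 changed at least 2-fold, 14 lists were called and 0 chromosomes; the list no longer called was the unfolded protein response (adjusted p = 0.0742), and HST2 of the chromatin list and MF(ALPHA)2 were called (0.0401 and 0.0433). The pairing was checked by the deviations of same-numbered libraries from their strain means, whose correlations were 0.09, -0.08 and 0.12. Not every library correlated best with its own number. With 3 libraries per strain this shows no clear pairing but cannot exclude a shared day or batch. Sequencing depth is unknown from TPM, so no limit from depth can be given.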

Other observations

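Of 15 pyrimidine genes 5 fell and 1 rose: the permease genes FCY2 and FUI1 fell by 2.16 and 1.17 on the log2 scale, and URA8 rose by 0.67 (limma; camera adjusted p = 0.0800 for the list, and 0.0352 without dChr library 3). Of 8 zinc regulon genes 3 fell, with ZRT2, a zinc transporter, at 77.5 ± 8.75 TPM against 142.9 ± 12.4 (camera adjusted p = 0.112). Of 22 genes of the TCA and glyoxylate cycles and gluconeogenesis 5 fell, with CIT2, the peroxisomal citrate synthase, at 270.9 ± 15.04 against 737 ± 20.1 TPM. Of 17 thiamine genes THI7, a thiamine transporter, fell by 0.71 and none rose. Of 44 kinetochore, cohesin and condensin genes 4 fell, among them CTF19, which overlaps IRC15, by 1.38 and IML3 by 0.78.

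Of 45 DNA replication genes CDC6 fell by 1.15 and TAH11 rose by 0.61. Of 36 nuclear genes of oxidative phosphorylation 2 rose and 2 fell, with COX4 at 29.0 ± 6.08 against 91.0 ± 7.09 TPM. Of 16 hexose transporter genes 2 rose and 2 fell, and HXT4 rose by 0.91. Of 26 ergosterol genes 2 rose and 3 fell, and the list median (-0.03) and camera differ in sign. Of 28 RNA surveillance genes 2 fell, including RRP4, which fell by 0.66. The calls of URA8, TAH11, HXT4 and RRP4 were each lost without dChr library 1 (adjusted p from 0.0521 to 0.0716) and without at least 1 other library. Limma called 0 of 18 seripauperin, 6 galactose and 6 mitochondrially encoded genes (1, 1 and 2 at an unadjusted p under 0.05), though OLI1, a mitochondrial gene, was called higher with median-ratio scaling (adjusted p = 0.0452) and GAL80, a galactose gene, lower without mitochondrial and non-coding transcripts (0.0477). Camera called none of the lists of this and the preceding paragraph (16 of all 32 lists had an unadjusted p under 0.05, 15 of them called). Among alpha-specific genes, SAG1 was at 11.1 ± 0.0704 against 12.9 ± 1.14 TPM and MF(ALPHA)2 at 9.08 ± 1.95 against 12.4 ± 2.42, and neither was called.

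The tests in the next paragraphs were chosen after their results or related values had been seen, including the counts over other splits of the libraries. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. Every other split has libraries of both strains on each side. A strain difference then adds to the spread within a side, which lowers the gene counts by construction, and part of it remains between the sides. These splits are therefore no measure of what chance alone would give. The strains gave 793 called transcripts against at most 6 in another split, and 268 changed at least 2-fold against at most 6; in each case 1 of 10 splits, the real one, was as large. They gave 15 called lists against at most 12 in another split (1 of 10). Camera at the preset correlation thus called many lists in splits that mix the strains, where part of the strain difference may remain. They gave 0 chromosomes against at most 0 (10 of 10).

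Chaperone genes stood above amino acid genes. A scale set by a few abundant RNAs moves all genes alike, so it cannot set 2 lists apart. The medians of these lists lay on opposite sides of that of all transcripts and 1.96 apart on the log2 scale (SD over members at most 0.963). This argues against such a scale as the whole cause of the gap between these lists. It does not bear on the number of rises and falls, which depended on the scaling. A general stress response in which ribosomal protein genes fall with biogenesis genes would give them like medians, and that of ribosomal proteins was higher by 0.700 (SD over ribosomal protein genes 0.489). The 20 chaperone genes outside the stress list had a median of 0.824 (15 rose), above that of all transcripts by little more than their SD of 0.852. The rise of chaperones was thus not confined to the 5 members that the lists share. A gene outside the stress list can still belong to the stress response, so whether these genes rose as part of it cannot be decided this way. The added chromosome was not tested apart from the rest of the strain, its culture or any unrecorded batch, since these go with the same 3 libraries.

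Among 647 annotated transcripts with a mean of at least 100 TPM, 20 had a library at least 4-fold from the mean of the other 2 of its strain while these agreed within 1.5-fold (24 cases). These genes were chosen after their values were seen. TDH3 was at 6.43 TPM in control library 2 against 15466 in the other controls, ENO2 at 411 in dChr library 1 against 14351, and TDH2 at 465 in control library 1 against 8796. The cases fell in 5 of the 6 libraries, 7 of them in control library 2. Reads assigned to an assembled transcript in place of the gene may account for them. A first test looked for an assembled transcript that moved the other way by 0.5 to 2 times the gap, and found it for 24 of 24 cases but for 23.6 on average over 720 permutations of the assembled columns, so it decides nothing. A second version, tried because of that, asked for an even sum (coefficient of variation of 15% or less). It found 14 cases against a median of 13 (permutation p = 0.372). A large and steady assembled transcript meets this rule without any exchange of reads. MSTRG.2768.1, at 3430 TPM in dChr library 3 and 3168 TPM in control library 1, was the best partner of SPI1, HXT7 and PGK1 in the former and of HHT1 in the latter. The second version therefore decides nothing either for the cases as a set, and the explanation stays open. For ENO2 the best partner was MSTRG.3208.1, at 14157 TPM in dChr library 1, where ENO2 was at 411. A steady transcript of that size would not give ENO2 an even sum, so this partner was not a steady one. This is 1 of the 14 cases with a partner, picked after its values were seen.

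Assembled transcripts found in the dChr libraries alone may be transcripts lost from single libraries. They may also be products of the added DNA, if its sequence was aligned to, which is not known here. At 1 TPM or more, 5 assembled transcripts were present in a single strain and at most 4 in another split (1 of 10 splits as large). At 5, 10 and 20 TPM the strains gave 3, 2 and 2, and 4, 5 and 4 of the 10 splits gave as many. The comparison therefore cannot separate these explanations, and coordinates would be needed.

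In chromosomal order of the 5082 tested protein-coding genes, rising genes followed each other in 26 pairs. In 10000 shuffles of the calls the mean was 9.20. Falling genes followed each other in 70 pairs against 46.9 (permutation p = 1e-04 for each direction, the smallest these shuffles can give). Untested genes and other transcripts may lie between the members of a pair. The shuffles treat calls as independent, while overlapping genes share reads. A part of shared reads in these pairs was not tested, so the p-values do not show shared regulation. Of the falling pairs 34 were on the same strand, 23 divergent and 13 convergent. Of the rising pairs 15 were on the same strand, 5 divergent and 6 convergent. Whether these orientations differ from those of all neighbouring genes was not tested.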
